A study of Homo sapiens with 4 samples.

How the data were processed

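Per the labels' protocols, U87 cells grown in DMEM with serum received either siRNA with oligofectamine, and total RNA was taken 72 hours later with an RNeasy kit. The same protocols give barcoded TruSeq Total RNA libraries that were pooled and read as 50 bp single-end reads. Per the submitters' processing notes, the authors used CASAVA 1.8.2, TopHat2 2.0.8b and HTSeq with the human genome build hg19 (GRCh37), and the design text names an HTSeq and DESeq pipeline run in duplicate. The deposited values are read counts per gene symbol, 1 column per library, which the authors left without normalization: they are whole numbers whose totals differ between libraries. The HTSeq version, the strand setting of the counting, the annotation release and the siRNA sequences are not given in the sources used here. A counting step of this kind leaves out reads that align to more than 1 place or overlap more than 1 gene, so genes with close paralogs or overlapping neighbours are under-counted, and without a strand setting reads of an overlapping gene on the other strand may be counted. The share of exon bases that a named gene shares with another annotated gene was therefore computed from GENCODE (release v44lift37).

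Each deposited column ended with 5 summary lines of the counter, which held 36.0 to 37.6% of all counts and were left out. Reads in no annotated feature were 11.6 to 12.8% and ambiguous reads 1.44 to 1.50% of uniquely aligned reads, and multiply aligned reads were 26.3 to 27.5% of all lines. Counts over genes came to 18670162 to 22858988 per library, with 3.83 to 4.19% in the 10 most abundant genes. All 4 libraries entered the 1 comparison, as 2 control siRNA and 2 PELP1 siRNA libraries, and none were merged. Precision at this depth is set by the spread between the libraries (biological coefficient of variation 5.23%) more than by counting for abundant genes, and by counting for genes of a few counts. Intervals cover counting error only.

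Of 23228 gene symbols, 13234 passed edgeR's filterByExpr (minimum count 10, minimum total count 15) and were tested, and 9994 were not. Counts were scaled by TMM and fitted with edgeR 4.0.16 (R 4.3.3) as a robust quasi-likelihood model with the group as the only term. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and CPM values are TMM-scaled. Every adjusted p of a single gene comes from this quasi-likelihood test unless DESeq2 (1.42.0) is named. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, over the 35 of 41 lists with at least 5 tested members, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry stood beside it. Fry asks whether a list's genes move one way on balance and does not compare them with other genes.

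The lists covered Wnt targets and components, partners of PELP1 in ribosome assembly, nucleolar factors, ribosomal proteins, DNA replication, mitosis, histones, p53 targets, regulators of apoptosis, mesenchymal state, matrix, stem cell markers, MYC targets, cholesterol and fatty acid synthesis, glycolysis and hypoxia, the respiratory chain, the unfolded protein and integrated stress responses, interferon, NF-kB, YAP, ERK, TGF-beta and estrogen targets, DNA repair, splicing, the proteasome, heat shock, mitochondrial and structural RNAs, and markers of immune, neuronal, oligodendrocyte, astrocyte, endothelial, epithelial and melanocyte cells. Of 1133 list members, 1109 were found among the symbols, in part by older names. The lists, the tests, the alternative settings and the rule for named genes were chosen before the data were examined. That rule takes PELP1, the 12 largest rises and 12 largest falls among called genes with a mean of at least 5 CPM and non-overlapping libraries (named RNA classes and uncharacterised loci left out), the 2 members of each list with the smallest adjusted p in each direction, and AXIN2, LEF1, MYC, CCND1 and CTNNB1. Some of the genes this rule names are not reported here. Other genes were named after their values were seen: EPHB2 in the report and the members of symbol families in the closing observations.

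The pipeline was tested on simulated data with the fitted dispersions. Of 50 planted changes each, it recovered 40.0% at 1.25-fold, 84.0% at 1.5-fold, 94.0% at 2-fold and 100% at 4-fold, and 15 of 174 calls (8.62%) were false. With no list changed 0 lists were called, and with the cholesterol list raised 1.5-fold that list alone was called, at an adjusted p of 0.0483 with an estimated correlation. Genes were drawn independently and with the same dispersion in both groups. These runs therefore do not show how often lists whose genes vary together are called falsely.

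Alternative settings fixed with the design were scaling by DESeq2 size factors, upper quartile or total counts; no filter or a stricter one (5 CPM in 2 libraries); DESeq2's Wald test; limma-voom; a fit that is not robust; a minimum fold of 1.5 with glmTreat; the replicate number as a block; leaving out each library; leaving out small and structural RNAs; and the other set tests. A pair of alternatives was added after the data were seen: removing each library's trend on transcript length and GC, over 12611 annotated genes, and leaving out the carriers of 2 words in 3' UTRs.

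Symbols were matched to GENCODE by name or by a synonym with a single current symbol (91.8% matched), and the canonical transcript gave each gene's length, GC and 3' UTR. All 7-base words were scanned over the 3' UTRs of 12231 tested genes other than PELP1. The log2 fold change was regressed on the presence of each word found in at least 50 genes (16189 words). Covariates were 3' UTR length, 3' UTR GC, transcript length, transcript GC and mean level. The scan was repeated on 20 shuffles of the fold changes and on 20 simulated data sets with a planted word, which ranked first in 20 of 20. Of 9 words under the lowest z of the shuffles, the 2 lowest were used as the words of the report. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Shares carry 95% Wilson intervals.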

Results

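RNA was sequenced from U87 MG cells, an established human glioblastoma line, after transfection with a control siRNA or with siRNA against PELP1. PELP1 encodes a scaffold protein that binds nuclear receptors and chromatin regulators and takes part in the assembly of the large ribosomal subunit. A small interfering RNA (siRNA) is a short double-stranded RNA that directs cleavage of a matching mRNA. Each group held 2 libraries of total RNA taken 72 hours after transfection. Reads assigned to genes numbered 19662271 and 22858988 in control libraries 1 and 2 and 19389684 and 18670162 in PELP1 siRNA libraries 1 and 2. Between 16229 and 16518 genes had at least 1 count in a library. Within a group the libraries differed beyond sampling noise, with a chi-square per gene of 2.09 for the control pair and 7.13 for the PELP1 siRNA pair, against 29.8 to 31.5 between groups. The design text gives only duplicates, so every p-value measures only the spread between these samples, which may be technical.

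The siRNA comparison asked which transcripts change when PELP1 is silenced, and in particular whether genes of Wnt/β-catenin signalling do. PELP1 itself (GRCh37 chromosome 17, 4573069 to 4607632, minus strand) fell from 76.0 ± 2.90 to 16.4 ± 1.79 CPM (mean ± SD, n = 2 libraries per group), where CPM is a gene's count scaled by library size. Its log2 fold change was -2.21 (SE 0.097, adjusted p = 8.32e-14). Its level fell by 78.4%. The single control libraries held 74.0 and 78.1 CPM and the single PELP1 siRNA libraries 15.2 and 17.7 CPM, from 1434, 1749, 299 and 336 counts.

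**Figure D1:**
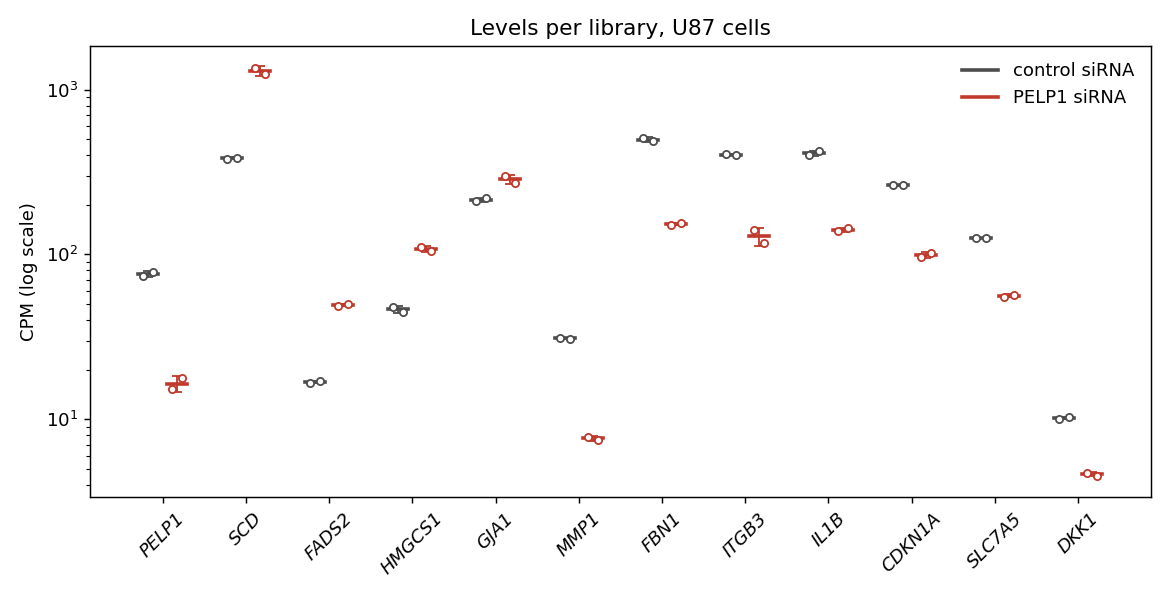
Level of 12 named genes in each library, in CPM on a log axis, with control siRNA and PELP1 siRNA libraries in separate colours, where bars mark each group mean and whiskers the SD (n = 2 libraries). PELP1 lies between 74.0 and 78.1 CPM in the control libraries and between 15.2 and 17.7 CPM in the PELP1 siRNA libraries.

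Of 13234 genes tested, 1712 were higher and 1980 lower with PELP1 siRNA, and 9542 did not pass the threshold (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Most changes were small: the median absolute log2 fold change of the changed genes was 0.40, 84 genes were higher and 176 lower by at least 2-fold, and 336 were higher and 626 lower by at least 1.5-fold. In 64.2% of the genes tested the libraries of one group all lay above those of the other, against 33.3% by chance, as did 3691 of the 3692 changed genes. Tested against a minimum fold of 1.5, 50 genes were higher and 156 lower. DESeq2 called 1135 higher and 1365 lower. Scaling by total counts alone gave 2272 higher and 1597 lower, so that 41.3% of the changed genes were lower instead of 53.6%. The counts moved with single libraries, and in these fits the lone sample is assumed to vary like the other group. They were 523 higher and 943 lower without control library 1, and 614 and 1075 without control library 2. They were 2724 higher and 2804 lower without PELP1 siRNA library 1, and 2604 and 2629 without PELP1 siRNA library 2.

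The largest rises among genes of at least 5 CPM were those of RANBP3L, SCD, FADS2 and CNIH2. RANBP3L rose from 4.86 ± 0.0115 to 20.1 ± 4.99 CPM (log2 fold change 2.05, SE 0.16, adjusted p = 1.03e-09, n = 2 per group). SCD (GRCh37 chromosome 10, 102106990 to 102124583, plus strand), the desaturase that makes monounsaturated fatty acids, rose from 384 ± 4.79 to 1300.2 ± 82.4 CPM (log2 fold change 1.76, SE 0.064, adjusted p = 6.35e-15), and its 3' UTR carries the 7-base word CTCAGTT. FADS2, a desaturase of polyunsaturated fatty acids, rose from 16.8 to 49.1 CPM (log2 fold change 1.55, SE 0.094, adjusted p = 1.72e-11) and shares 4.64% of its exon bases with FADS1 on the opposite strand. CNIH2, an auxiliary protein of AMPA receptors, rose from 2.60 to 7.62 CPM (log2 fold change 1.53, SE 0.19, adjusted p = 2.14e-06), with 9.77% of its exon bases shared with YIF1A on the opposite strand. SC4MOL, a methylsterol oxidase of cholesterol synthesis, rose by 1.24 on the log2 scale and HMGCS1, which makes the precursor of mevalonate, by 1.22. The imprinted small GTPase DIRAS3 (1.37), the lens filament protein BFSP1 (1.27), the cold-sensing channel TRPM8 (1.21), the ganglioside sialyltransferase ST8SIA1 (1.16), the glutathione transferase GSTA4 (1.14) and the non-coding transcript NCRNA00263 (1.22) completed the 12 largest rises, with adjusted p from 4.20e-08 to 6.41e-05. NCRNA00263 starts at 102132856 on chromosome 10, downstream of SCD on the same strand, and its rise was not tested apart from that of SCD.

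After PELP1, the largest falls among genes of at least 5 CPM were those of MMP1, SERPIND1, FBN1, PLXNA4 and ITGB3. MMP1 (GRCh37 chromosome 11, 102660132 to 102668891, minus strand), the interstitial collagenase, fell from 30.9 ± 0.113 to 7.65 ± 0.238 CPM (log2 fold change -2.01, SE 0.11, adjusted p = 4.28e-12, n = 2 per group). FBN1 (GRCh37 chromosome 15, 48700510 to 48937918, minus strand), the fibrillin of extracellular microfibrils, fell from 498 ± 16.1 to 153 ± 2.71 CPM (log2 fold change -1.70, SE 0.064, adjusted p = 8.22e-15). ITGB3, a beta subunit of integrins that bind vitronectin, fell from 403 to 129 CPM (log2 fold change -1.65, SE 0.074, adjusted p = 1.00e-13). IL1B, the cytokine interleukin-1 beta, fell from 412 ± 14.9 to 141 ± 3.93 CPM (log2 fold change -1.55, SE 0.065, adjusted p = 6.45e-14). SERPIND1, a thrombin inhibitor, fell from 31.4 to 9.51 CPM (log2 fold change -1.72, SE 0.11, adjusted p = 3.26e-11) and lies within PI4KA on the opposite strand without shared exons. DUSP3, a dual-specificity phosphatase, fell from 269 to 96.0 CPM (log2 fold change -1.49, SE 0.066, adjusted p = 1.00e-13). The semaphorin receptor PLXNA4 (-1.65), the imprinted long non-coding RNA MEG3 (-1.56), the nucleotide sugar transporter SLC35D1 (-1.53), the collagen-binding integrin subunit ITGA10 (-1.51) and EVI2B (-1.52), which lies within NF1 on the opposite strand without shared exons, completed the list, with adjusted p from 3.22e-11 to 3.56e-07.

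The 3' UTRs of the fallen genes were rich in some words of 7 bases, of which CTCAGTT and GCCTTGA stood out most; both also occur in the PELP1 mRNA. On the minus strand of chromosome 17 (GRCh37), CTCAGTT lies at 4594686 to 4594692 in exon 2 of PELP1 and GCCTTGA at 4580065 to 4580071 in exon 6 and 4576546 to 4576552 in exon 15, all in coding sequence. Either word stood in the 3' UTR of 264 of 574 genes lower by at least 1.5-fold (46.0%, 95% Wilson interval 42.0 to 50.1%), of 22.8% of the genes not past the threshold (21.9 to 23.7%) and of 19.4% of the genes higher by at least 1.5-fold (15.3 to 24.1%). Of the 11 largest falls other than PELP1, 10 have an annotated 3' UTR and 6 carry a word: MMP1, FBN1, ITGB3 and SLC35D1 carry CTCAGTT, and PLXNA4 and DUSP3 carry both. Of the 12 largest rises, 11 have an annotated 3' UTR and 1 carries a word (SCD). The words were chosen on these same fold changes, and the shares are not adjusted for 3' UTR length or GC. Most genes that carry a word were not called lower.

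**Figure D2:**
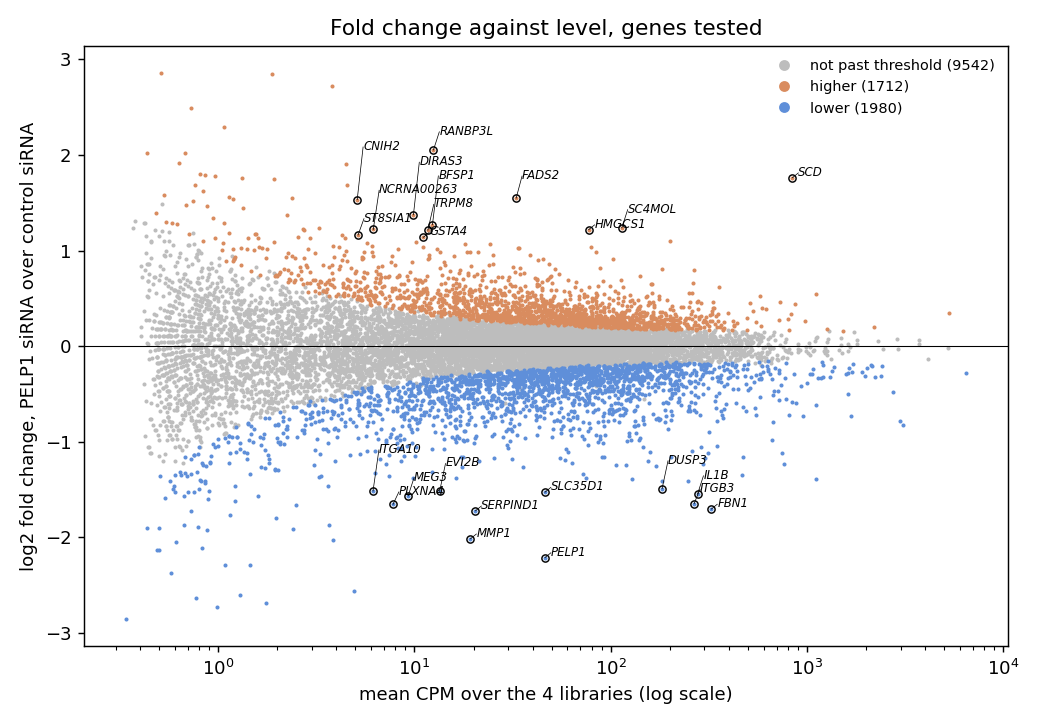
Log2 fold change (PELP1 siRNA over control siRNA) against mean CPM over the 4 libraries on a log axis, 1 point per gene tested, coloured as higher (1712), lower (1980) or not past the threshold (9542). The circled genes are the 12 largest rises, up to 2.05, and the 12 largest falls, down to -2.21, among genes of at least 5 CPM.

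Genes induced by Wnt/β-catenin transcription moved in both directions. Of 24 tested, 3 were higher, 7 lower and 14 did not pass the threshold (3 higher and 8 lower adjusted over the list alone). DKK1, a secreted Wnt antagonist, fell from 10.2 to 4.63 CPM (log2 fold change -1.13, SE 0.15, adjusted p = 3.54e-06). TCF7, a transcription factor that binds β-catenin, fell from 89.7 to 59.6 CPM (-0.59, adjusted p = 3.18e-06). TCF7 carries GCCTTGA and shares 2.08% of its exon bases with SKP1 on the opposite strand. MYC (-0.47, adjusted p = 1.68e-04) and the cyclin CCND1 (-0.33, adjusted p = 1.90e-04), which carries GCCTTGA, also fell. SOX9 (0.58, adjusted p = 4.91e-05) and the apoptosis inhibitor BIRC5 (0.42, adjusted p = 4.48e-05) rose, as did ID2 (0.36, adjusted p = 0.00282), whose adjusted p was 0.0714 without control library 1 and 0.156 without control library 2. AXIN2, a feedback inhibitor of the pathway, stood at 4.71 CPM with control siRNA and 4.78 CPM with PELP1 siRNA (log2 fold change 0.021, adjusted p = 0.940, and -0.020 without PELP1 siRNA library 1). LEF1 had a log2 fold change of -0.43 (adjusted p = 0.0597, and 0.0468 with a stricter filter on low counts). CTNNB1, which encodes β-catenin, had one of -0.082 (adjusted p = 0.340, and 0.0415 with the length and GC trend removed). Its log2 fold change ranged from -0.115 to -0.048 over the fits that leave out 1 library. As a set the targets had a median log2 fold change of -0.063 and were not called against other genes (camera with a preset correlation, adjusted p = 0.356), while fry, which does not compare them with other genes, gave an adjusted p of 0.00586 downward. Of the 7 lower members, 3 carry a word (TCF7, CCND1 and EPHB2).

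Among 39 ligands, receptors and transducers of the Wnt pathway, 7 were higher, 7 lower and 25 did not pass the threshold (7 higher and 9 lower adjusted over the list alone). CTNNBIP1, which blocks the binding of β-catenin to TCF factors, rose from 12.5 to 24.7 CPM (0.98, adjusted p = 1.38e-06), and the secreted SFRP2 rose from 8.67 to 14.5 CPM (0.74, adjusted p = 8.41e-05). PORCN, the acyltransferase that modifies Wnt ligands, fell from 27.0 to 14.1 CPM (-0.93, adjusted p = 3.01e-07), and the ligand WNT5A, which carries CTCAGTT, fell from 407 to 284 CPM (-0.52, adjusted p = 1.27e-06). The list had a median log2 fold change of -0.082 and a camera adjusted p of 0.575.

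Genes of lipid synthesis rose, among them those of both cholesterol and fatty acid synthesis. Of 24 genes of cholesterol synthesis and uptake, 16 were higher, 1 lower and 7 did not pass the threshold (18 higher and 1 lower adjusted over the list alone). The list's median log2 fold change was 0.59 (camera, adjusted p = 1.88e-22; adjusted p = 0.262 with an estimated correlation). SC4MOL rose from 67.7 to 159.9 CPM (adjusted p = 1.44e-11) and HMGCS1 (GRCh37 chromosome 5, 43287572 to 43313614, minus strand) from 46.4 to 108 CPM (adjusted p = 4.37e-11). Of 12 genes of fatty acid synthesis, 8 were higher, 0 lower and 4 did not pass the threshold (9 higher and 1 lower adjusted over the list alone), led by SCD and FADS2, with a median of 0.44 (adjusted p = 2.82e-13; adjusted p = 0.262 with an estimated correlation).

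Most targets of the stress factor ATF4 and fewer than 1 in 2 of those of NF-kB fell past the threshold, and none rose past it. Of 33 genes of the integrated stress response and amino acid starvation, 0 were higher, 26 lower and 7 did not pass the threshold (0 higher and 27 lower adjusted over the list alone). Their median log2 fold change was -0.35 (camera, adjusted p = 5.80e-14; adjusted p = 0.275 with an estimated correlation). SLC7A5, a transporter of large neutral amino acids, fell from 125 to 56.2 CPM (-1.15, adjusted p = 3.84e-11). MTHFD2, a mitochondrial enzyme of folate metabolism, fell from 122 to 64.2 CPM (-0.93, adjusted p = 2.26e-09). MTHFD2 carries both words and shares 11.6% of its exon bases with SLC4A5 on the opposite strand. Of 25 cytokines and other genes induced by NF-kB, 0 were higher, 12 lower and 13 did not pass the threshold (0 higher and 12 lower adjusted over the list alone), with a median of -0.26 (adjusted p = 2.82e-13; adjusted p = 0.262 with an estimated correlation). CSF3, the granulocyte colony-stimulating factor, fell from 1075 to 458 CPM (-1.23, adjusted p = 1.10e-12), beside IL1B. A word stood in the 3' UTR of 3 of the 26 lower ATF4 targets and 1 of the 12 lower NF-kB genes.

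Mesenchymal genes, YAP targets and TGF-beta targets fell more often than they rose. Of 26 mesenchymal genes, 4 were higher, 15 lower and 7 did not pass the threshold (4 higher and 15 lower adjusted over the list alone). Their median log2 fold change was -0.25 (camera, adjusted p = 7.44e-05; adjusted p = 0.275 with an estimated correlation). PLAU, the urokinase plasminogen activator, fell from 415 to 177 CPM (-1.23, adjusted p = 1.57e-12). PLAU carries CTCAGTT and shares 31.0% of its exon bases with C10orf55 on the opposite strand. The matrix protein SPARC rose from 900.0 to 1311 CPM (0.54, adjusted p = 2.48e-07) and the cadherin CDH11, which carries CTCAGTT, from 9.99 to 18.3 CPM (0.88, adjusted p = 6.43e-06). Of 23 YAP and TEAD targets, 0 were higher, 13 lower and 10 did not pass the threshold (0 higher and 14 lower adjusted over the list alone), with a median of -0.28 (adjusted p = 9.19e-06; adjusted p = 0.275 with an estimated correlation). AMOTL2 (carrying GCCTTGA) fell by 0.85 and ASAP1 (carrying CTCAGTT) fell by 0.57 on the log2 scale, and 8 of the 13 lower YAP targets carry a word. Of 20 TGF-beta targets, 3 were higher, 8 lower and 9 did not pass the threshold (3 higher and 10 lower adjusted over the list alone), with a median of -0.22 (adjusted p = 0.00745; adjusted p = 0.417 with an estimated correlation). LTBP2, of the family named latent TGF-beta binding proteins, carries GCCTTGA and fell from 110.4 to 58.0 CPM (-0.93, adjusted p = 1.98e-09). With the carriers of either word left out, the TGF-beta list had a median of -0.17 over 13 members, with an adjusted p of 0.129.

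Genes induced by p53, genes induced by ERK and anti-apoptotic genes also fell more often than they rose. Of 29 p53 targets, 3 were higher, 10 lower and 16 did not pass the threshold (3 higher and 12 lower adjusted over the list alone). The list's median log2 fold change was -0.099 (camera, adjusted p = 0.00134; adjusted p = 0.275 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, fell from 263 to 99.4 CPM (-1.41, adjusted p = 3.06e-13) and ZMAT3 from 161 to 80.6 CPM (-0.99, adjusted p = 3.43e-10), and both carry CTCAGTT. CCNG1, a cyclin induced by p53, rose from 209 to 307 CPM (0.56, adjusted p = 1.02e-06). Of 19 genes induced by ERK signalling, 1 was higher, 8 lower and 10 did not pass the threshold (2 higher and 10 lower adjusted over the list alone), with a median of -0.20 (adjusted p = 0.00242; adjusted p = 0.286 with an estimated correlation). The ERK phosphatase DUSP6, with CTCAGTT, fell by 0.74 and the inhibitor SPRED1, with GCCTTGA, fell by 0.73. The 1 higher member, the transcription factor ETV5 (0.18, adjusted p = 0.0496), had an adjusted p of 0.509 without control library 1, 0.311 without control library 2, 0.0874 with the word carriers left out and 0.0502 with DESeq2 size factors. Of 12 anti-apoptotic genes, 1 was higher, 8 lower and 3 did not pass the threshold (1 higher and 8 lower adjusted over the list alone), with a median of -0.28 (adjusted p = 0.0183; adjusted p = 0.417 with an estimated correlation). BIRC2, an inhibitor of apoptosis, fell by 0.49, and BCL2L2, which carries GCCTTGA and shares 16.8% of its exon bases with the read-through gene BCL2L2-PABPN1 on the same strand, fell by 0.62. With the carriers of either word left out, fewer members were tested (21 p53, 13 ERK and 8 anti-apoptotic genes). The medians were then -0.11, -0.15 and -0.17, with adjusted p of 0.217, 0.0818 and 0.143. Of 22 pro-apoptotic genes, 6 were higher, 0 lower and 16 did not pass the threshold (6 higher and 0 lower adjusted over the list alone; adjusted p = 0.0561).

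Fewer than 1 in 2 genes of the respiratory chain rose past the threshold. Of 44 nuclear-encoded subunits, 21 were higher, 1 lower and 22 did not pass the threshold (27 higher and 1 lower adjusted over the list alone). The list's median log2 fold change was 0.21 (camera, adjusted p = 3.07e-06; adjusted p = 0.652 with an estimated correlation and 0.145 by fry). ATP5A1, a subunit of ATP synthase, rose from 508 to 669.8 CPM (0.40, adjusted p = 2.14e-05) and NDUFB5, a subunit of complex I with CTCAGTT, from 85.2 to 119 CPM (0.48, adjusted p = 1.99e-05). NDUFA1, also of complex I and carrying CTCAGTT, fell from 81.5 to 35.7 CPM (-1.19, adjusted p = 3.65e-10). The median of the list differed by 0.127 on the log2 scale between PELP1 siRNA libraries 2 and 1 and by 0.001 between the control libraries.

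Cell division and ribosome assembly lists lay near the threshold. Of 51 genes of mitosis, 10 were higher, 3 lower and 38 did not pass the threshold (10 higher and 3 lower adjusted over the list alone). Their median log2 fold change was 0.095 (camera, adjusted p = 0.0470; adjusted p = 0.612 with an estimated correlation). The transcription factor MYBL2 rose from 86.4 to 139 CPM (0.69, adjusted p = 2.99e-07) and the cyclin CCNB2 by 0.41. The mitotic kinesin KIF20A fell by 0.61 (3.43% of its exon bases shared with BRD8 on the opposite strand), and CKS1B, a cofactor of cyclin-dependent kinases that carries GCCTTGA, fell by 0.74. The adjusted p of the mitosis list was 0.116 without control library 1, 0.112 without PELP1 siRNA library 1, 0.0655 with a stricter filter, 0.132 with the length and GC trend removed (median 0.091) and 0.0993 with the word carriers left out (median 0.0998, 42 members). Of 63 nucleolar factors of ribosome assembly, 1 was higher, 14 lower and 48 did not pass the threshold (1 higher and 14 lower adjusted over the list alone), with a median of -0.071 (adjusted p = 0.0470; adjusted p = 0.612 with an estimated correlation). TSR1, which carries both words and shares 23.9% of its exon bases with SRR on the opposite strand, fell by 0.67, and NIP7, which carries GCCTTGA and shares 18.4% with COG8 on the opposite strand, fell by 0.69. The adjusted p of the ribosome assembly list was 0.113 without control library 2, 0.102 without PELP1 siRNA library 1, 0.0730 with scaling by total counts and 0.0655 with a stricter filter. Of the 6 partners of PELP1 in ribosome assembly, 1 was higher, 0 lower and 5 did not pass the threshold (1 higher and 0 lower adjusted over the list alone; adjusted p = 0.894, upward, with a mean of 0.014 and a median of -0.050). The higher one, SENP3 (0.33, adjusted p = 0.0201), shares 41.7% of its exon bases with SENP3-EIF4A1 on the same strand and had an adjusted p of 0.162 without control library 1, 0.243 without control library 2 and 0.106 with DESeq2.

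Genes of the ribosomal proteins were not called as sets. Of 45 large-subunit proteins, 6 were higher, 2 lower and 37 did not pass the threshold (6 higher and 1 lower adjusted over the list alone; camera, adjusted p = 0.0828, and 5.93e-06 without PELP1 siRNA library 1). Of 31 small-subunit proteins, 3 were higher, 0 lower and 28 did not pass the threshold (2 higher and 0 lower adjusted over the list alone; adjusted p = 0.160, and 5.84e-04 without PELP1 siRNA library 1). The medians of these lists differed by 0.174 and 0.180 on the log2 scale between PELP1 siRNA libraries 2 and 1.

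Several other lists held strong single changes without passing as sets. Of 35 matrix genes, 4 were higher, 11 lower and 20 did not pass the threshold (4 higher and 11 lower adjusted over the list alone; camera, adjusted p = 0.116, and 0.0325 without control library 2). The collagen COL5A2 rose from 127 to 274 CPM (1.10, adjusted p = 1.23e-11) and the laminin LAMB2 fell from 109 to 62.8 CPM (-0.80, adjusted p = 3.25e-08). Of 14 stem cell markers, 1 was higher, 4 lower and 9 did not pass the threshold (2 higher and 4 lower adjusted over the list alone; adjusted p = 0.0740, and 0.00879 with the word carriers left out). ALDH1A3, an aldehyde dehydrogenase of retinoic acid synthesis, fell from 876 to 445 CPM (-0.98, adjusted p = 3.26e-11) and the receptor NOTCH1 fell by 0.97. Of 35 glycolysis and hypoxia genes, 4 were higher, 8 lower and 23 did not pass the threshold (4 higher and 8 lower adjusted over the list alone; adjusted p = 0.116, and 0.0193 without PELP1 siRNA library 2). The phosphofructokinase PFKM, which carries CTCAGTT and shares 7.12% of its exon bases with SENP1 on the opposite strand, fell from 168 to 71.3 CPM (-1.24, adjusted p = 1.06e-11), and VEGFA fell from 463 to 305 CPM (-0.60, adjusted p = 9.23e-08). Of 25 genes of the unfolded protein response, 0 were higher, 7 lower and 18 did not pass the threshold (0 higher and 7 lower adjusted over the list alone; adjusted p = 0.0828). The sensor ERN1, which carries both words, fell by 1.07, and EDEM1 fell by 0.42. Of 10 estrogen receptor targets, 1 was higher, 3 lower and 6 did not pass the threshold (2 higher and 5 lower adjusted over the list alone; adjusted p = 0.894, downward, with a median of -0.13 and a mean of 0.27). The chemokine CXCL12 rose from 0.452 to 3.31 CPM (2.85, adjusted p = 2.07e-07).

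The remaining pathway lists were not called. Of 46 DNA replication genes, 8 were higher, 5 lower and 33 did not pass the threshold (8 higher and 5 lower adjusted over the list alone; camera, adjusted p = 0.243). The cell cycle factor E2F2 rose by 0.76 and the helicase subunit MCM4, with CTCAGTT, fell by 0.52. Among 34 DNA repair genes, 5 were higher, 6 lower and 23 did not pass the threshold (6 higher and 6 lower adjusted over the list alone; adjusted p = 0.757). The double-strand break protein RAD50, with both words, fell by 0.48. Of 24 MYC targets, 3 were higher, 6 lower and 15 did not pass the threshold (3 higher and 6 lower adjusted over the list alone; adjusted p = 0.519). The ornithine decarboxylase ODC1 fell from 459 to 279.7 CPM (-0.72, adjusted p = 8.17e-09). Of 37 interferon-induced genes, 4 were higher, 5 lower and 28 did not pass the threshold (4 higher and 5 lower adjusted over the list alone; adjusted p = 0.356). Of these, IFIT1 rose by 0.69 and OASL fell by 0.67. Of 19 heat shock genes, 1 was higher, 7 lower and 11 did not pass the threshold (2 higher and 7 lower adjusted over the list alone; adjusted p = 0.323). The chaperone HSPB8 fell by 0.52. Among 43 splicing genes 4 were higher, 3 lower and 36 did not pass the threshold (1 higher and 1 lower adjusted over the list alone; adjusted p = 0.678). Among 31 proteasome subunits 3 were higher, 2 lower and 26 did not pass the threshold (1 higher and 0 lower adjusted over the list alone; adjusted p = 0.554). Of 14 histone genes, 0 were higher, 1 lower and 13 did not pass the threshold (0 higher and 0 lower adjusted over the list alone; adjusted p = 0.466).

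Few markers of other cell types had enough counts to be tested. Of 6 astrocyte markers tested, 3 were higher, 0 lower and 3 did not pass the threshold (3 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 0.31 (camera, adjusted p = 0.0243; adjusted p = 0.417 with an estimated correlation). SOX9 rose from 24.4 to 36.4 CPM and the gap junction protein GJA1 from 215 to 286 CPM (0.41, adjusted p = 5.08e-05). Of 6 neuronal markers, 1 was higher, 1 lower and 4 did not pass the threshold (2 higher and 1 lower adjusted over the list alone; adjusted p = 0.894): MAP2 rose by 0.65 and SNAP25 fell by 0.63. Of 5 oligodendrocyte markers, 1 was higher, 1 lower and 3 did not pass the threshold (1 higher and 1 lower adjusted over the list alone; adjusted p = 0.519, downward, with a median of 0.015 and a mean of -0.085). The receptor PDGFRA rose (0.69, adjusted p = 0.0218; 0.391 without control library 2, where the log2 fold change was 0.41, 0.0523 without PELP1 siRNA library 1 and 0.182 with DESeq2). The proteoglycan CSPG4 fell from 115 to 66.8 CPM (-0.79, adjusted p = 2.13e-08). Too few members of the other lists were tested for a set test. Of 4 immune markers 1 was higher (TMEM119, 2.76 to 6.07 CPM) and 3 did not pass. Of 4 endothelial markers 1 was lower (KDR, -0.50, adjusted p = 0.00380, and 0.103 without control library 1) and 3 did not pass. Of 3 melanocyte markers 1 was lower (MITF, -0.48) and 2 did not pass. Of 3 epithelial markers 1 was higher (EPCAM, adjusted p = 0.0188, and 0.211 without control library 1, 0.0585 without control library 2 and 0.0627 without PELP1 siRNA library 1), 1 was lower (CLDN4, adjusted p = 0.0432, and 0.0635, 0.425 and 0.222 without the same libraries and 0.0547 with scaling by total counts; it carries GCCTTGA) and 1 did not pass. Of 4 structural and nuclear RNAs 1 was lower, the nuclear RNA NEAT1 (-0.62, adjusted p = 0.00311). NEAT1 had a log2 fold change of -0.49 (adjusted p = 0.495) without PELP1 siRNA library 1, -0.75 (0.391) without PELP1 siRNA library 2 and -0.50 (0.207) with the length and GC trend removed. For these 5 lists the counts adjusted over the list alone were the same. Median and mean differed in sign for structural and nuclear RNAs (0.064 and -0.019), endothelial markers (0.0048 and -0.019) and melanocyte markers (-0.042 and 0.053). No transcript of the mitochondrial genome was among the gene symbols.

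**Figure D3:**
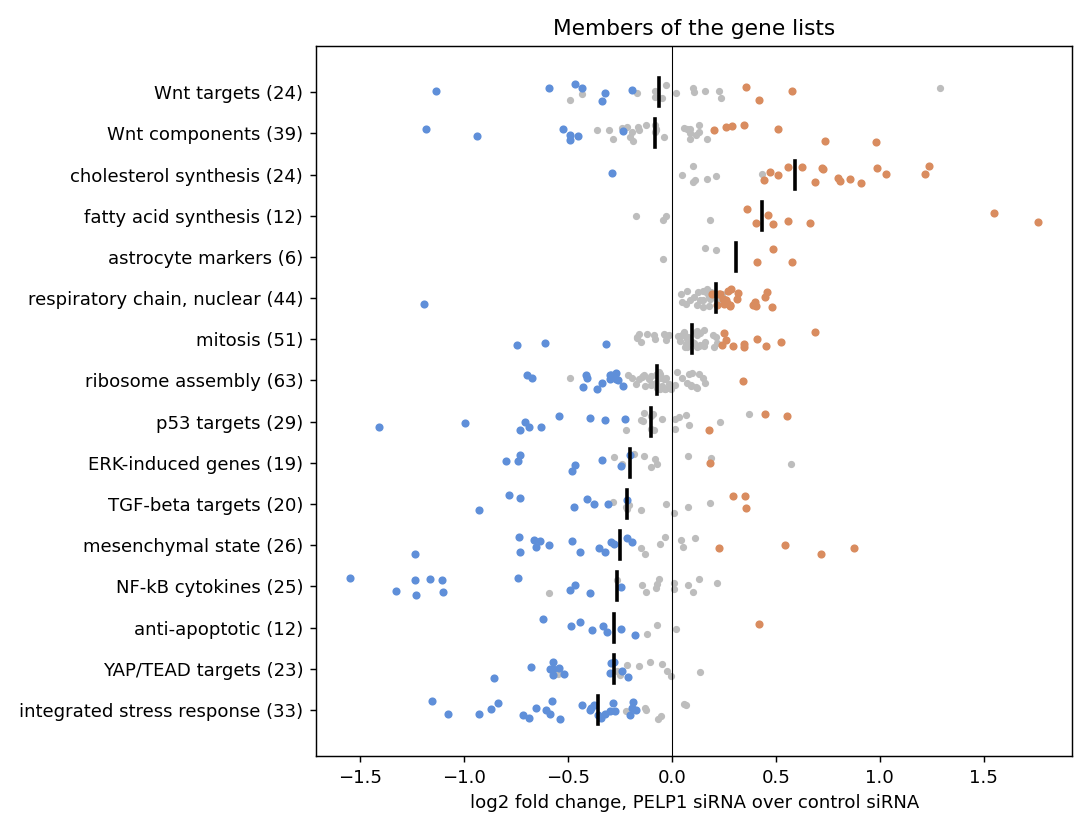
Log2 fold change (PELP1 siRNA over control siRNA) of each tested member of the 14 called lists and both Wnt lists, 1 point per gene with small vertical offsets, orange for genes called higher, blue for genes called lower and grey for the rest, with the median as a black bar and the number tested in brackets. The 24 cholesterol genes have the highest median, 0.59, and the 33 integrated stress genes the lowest, -0.35.

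Of 35 lists tested with camera at a preset correlation of 0.01, 14 were called, 5 upward and 9 downward. With an estimated correlation 0 of the 14 calls held, but that version of the test has little power with 2 libraries per group. The cholesterol and fatty acid lists had estimated correlations of -0.0095 and -0.020, under the preset 0.01. Correlation between their genes is therefore not why these 2 lists were no longer called. By fry, which asks only whether a list's genes move one way, 15 lists passed.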

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

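The trend-removed and carriers-left-out alternatives were chosen after the data were seen, and all others were planned. PELP1 fell in every alternative, with log2 fold changes of -2.32 to -2.10 over the fits that leave out 1 library, and no gene called in the report was called in the opposite direction in any alternative. Counts of changed genes stayed within 1.5 times of 3692 with other scalings, filters, limma-voom, a fit that is not robust, and small RNAs left out. DESeq2 called 1135 genes higher, with 11447 genes given no adjusted p. Removal of the length and GC trend gave 2881 higher; the cause was not tested. A minimum fold of 1.5 left 206 changed genes, 50 higher and 156 lower, since most changes were smaller than that. Leaving out the word carriers gave 1285 lower genes and 9 lists past the threshold, with fewer genes tested (10146). Leave-one-out fits gave 1466 to 5528 changed, 523 to 2724 higher and 943 to 2804 lower genes, where leaving out a library of the more variable PELP1 siRNA pair raised the counts. With the replicate number as a block, as for paired samples, 3581 genes changed and 14 of 14 list calls were kept. The labels give no pairing. Deviations from the group mean correlated at -0.031 between control library 1 and PELP1 siRNA library 1. With 2 libraries per group the deviations of library 2 mirror those of library 1, so this is a single comparison. With an estimated correlation 0 lists passed. In the simulation the planted list had a camera adjusted p of 0.0483 this way, against 8.53e-187 at the preset correlation. That version has little power here, so not passing it says little against a list. The cause was not tested for each list. Fry called the Wnt targets (0.00586), and it does not compare them with other genes. All 14 list calls were kept with DESeq2 size factors, upper quartile, no filter, limma-voom and without PELP1 siRNA library 2. Scaling by total counts kept 13, the stricter filter 11, trend removal 13, carriers left out 8 and fry 11, and under the stricter filter and with carriers left out the astrocyte list had too few members to test. Lists not called in the report passed in some alternatives: large-subunit proteins (0.0424 with no filter, 0.0382 with limma-voom), pro-apoptotic genes (0.0268, 0.0397), the unfolded protein response (0.0234, 0.0397, and 0.0214 with the trend removed) and stem cell markers (0.0303 with the stricter filter). Directions that reversed were those of lists not past the threshold, and the cause was not tested: neuronal markers (stricter filter 0.892, trend 0.977, carriers out 0.930, fry 0.980), Wnt components, small-subunit proteins and matrix (trend 0.977, 0.977 and 0.977), proteasome (trend 0.725), DNA repair (carriers out 0.826) and PELP1 partners (fry 0.996). Leave-one-out ranges of the adjusted p were 0.680 to 0.955 for neuronal markers, 0.561 to 0.970 for estrogen targets, 0.491 to 0.971 for histones, 0.687 to 0.941 for PELP1 partners, 5.84e-04 to 0.932 for small-subunit proteins, 0.338 to 0.827 for DNA repair, 0.292 to 0.827 for splicing and 0.0999 to 0.827 for the proteasome, and AXIN2 ranged from -0.020 to 0.068 in log2 fold change. At this depth and with 2 libraries per group, the smallest simulated changes were recovered in 40.0% of cases. That share does not carry over to the data. The simulation gave 174 calls against 3692, and with fewer calls the same adjusted p stands at a smaller unadjusted p. Some smaller changes were called in the data, such as that of CA12 (log2 fold change -0.24, adjusted p = 0.00511), though not in the fits that leave out a control library. How often changes of the smallest simulated size were missed was not measured. Changes of genes under the count filter were not tested.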

Other observations

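The 12 gene families here, the tests of 2 words in 3' UTRs and of all words carried by risen lipid genes, and the trend-removed and carriers-left-out fits were chosen only after the data were seen. The families were tested with camera at the preset correlation. Some secreted and membrane-bound matrix proteases fell: of 24 matrix metalloproteinases and ADAMTS proteases, 1 was higher, 10 lower and 13 did not pass the threshold (median log2 fold change -0.25, adjusted p = 2.22e-08; adjusted p = 0.209 with an estimated correlation). MMP3, the stromelysin, had 1564 and 1655 CPM with control siRNA and 614 and 619 CPM with PELP1 siRNA (log2 fold change -1.39). The aggrecanase ADAMTS5 (-1.34), ADAMTS1 (-1.20), ADAMTS18 (-1.10) and the membrane-bound MMP14 (-0.65) also fell, while ADAMTS3 rose (0.77), and 3 of the 10 lower members carry CTCAGTT or GCCTTGA. Of 19 integrin subunits, 3 were higher, 8 lower and 8 did not pass the threshold (median -0.31, adjusted p = 8.13e-04; adjusted p = 0.209 with an estimated correlation): the collagen-binding ITGA2 fell (-1.25) beside ITGB3 and ITGA10, and ITGB8 rose (1.03). Of 25 semaphorins and their plexin receptors, 3 were higher, 9 lower and 13 did not pass the threshold (adjusted p = 0.00164; adjusted p = 0.209 with an estimated correlation), with PLXNA2 at -1.01 and PLXNA3 at -0.91. Of 14 serpins, 4 were higher, 5 lower and 5 did not pass the threshold (adjusted p = 0.00583; adjusted p = 0.209 with an estimated correlation), with SERPINB2, an inhibitor of plasminogen activators, at -1.39 and SERPINE2 at 0.62. These families were chosen with genes of the report in them and after the values of their other members were seen. Leaving out the named genes therefore does not undo that choice. Without the genes that the naming rule takes, the adjusted p was 4.79e-06 for the proteases (23 genes), 0.147 for the integrins (17), 0.0143 for the semaphorins and plexins (24) and 0.559 for the serpins (12). None of these families changed the sign of its median under the other scalings. With the length and GC trend removed, the median went from -0.25 to -0.17 for the proteases and from -0.31 to -0.25 for the integrins. It went from -0.24 to -0.10 for the semaphorins and plexins and from -0.14 to -0.16 for the serpins. Either word stood in the 3' UTR of 3 of the 8 lower integrins and 4 of the 9 lower semaphorins and plexins. Of the 5 lower serpins 0 carry one.

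Some genes of cilium transport rose: of 21 intraflagellar transport and BBSome genes, 9 were higher, 0 lower and 12 did not pass the threshold (median 0.17, adjusted p = 9.49e-04; adjusted p = 0.209 with an estimated correlation), with IFT57 at 0.62 and BBS4 at 0.57. Of 32 protocadherins, 7 were higher, 0 lower and 25 did not pass the threshold (adjusted p = 0.0165; adjusted p = 0.650 with an estimated correlation), and their median differed by -0.26 on the log2 scale between PELP1 siRNA libraries 2 and 1. Of 75 mitochondrial ribosomal proteins, 18 were higher, 1 lower and 56 did not pass the threshold (median 0.15, adjusted p = 7.24e-04; adjusted p = 0.650 with an estimated correlation), and their median differed by 0.110 between the same libraries. The other families were not called. Among 17 cytosolic aminoacyl-tRNA synthetases 2 were higher, 7 lower and 8 did not pass the threshold (adjusted p = 0.0833), and among 17 mitochondrial ones 0 were higher, 2 lower and 15 did not pass the threshold (adjusted p = 0.813; the median of the latter changed sign with scaling by total counts). Among 13 glutathione transferases 2 were higher, 0 lower and 11 did not pass the threshold (adjusted p = 0.243). Among 372 ZNF genes 14 were higher, 28 lower and 330 did not pass the threshold (adjusted p = 0.979; the sign of their median also changed with that scaling). Among 51 RAB GTPases 7 were higher, 6 lower and 38 did not pass the threshold (adjusted p = 0.246).

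A scan of words in 3' UTRs asked whether the fall of 626 genes by at least 1.5-fold goes with siRNA seed matches, short stretches through which an siRNA can silence other mRNAs. CTCAGTT (2103 genes, z = -11.57) and GCCTTGA (1459 genes, z = -11.42) stood apart from the lowest z of 20 shuffles (-4.76). Each ranked first or second in the other part when the genes were split at random. Both occur in the PELP1 mRNA, as 22.4% of scored words do. The adjusted differences in log2 fold change were -0.108 for CTCAGTT and -0.120 for GCCTTGA. Genes with CTCAGTT only, GCCTTGA only or both were called lower in 24.6%, 25.3% and 32.9% of cases, against 11.8% with neither word. They were called higher in 10.3%, 9.8% and 7.6%, against 14.7%. Most carriers were thus not called lower. Of the 574 genes lower by at least 1.5-fold with an annotated 3' UTR, 31.0% carry CTCAGTT (27.4 to 34.9%). Direct silencing through this word in these 3' UTRs as the whole cause is therefore excluded. That share does not bound indirect falls, downstream of silenced carriers, which were not tested. Of the 594 with an annotated length, 86.9% stayed lower by at least 1.5-fold after the length and GC trend was removed. The trend as the whole cause is excluded, but not as a part of the falls. Either word was carried by 46.0% of the 574 against 22.8% of genes not past the threshold. The words were chosen on these same fold changes. Unlike the z of the scan, these shares are not adjusted for 3' UTR length or GC. Off-target silencing through seeds may account for part of the falls, but these shares do not measure how large a part. A further word, AGTTATT, had a z of -5.63 with both fitted and is not in these shares. In the PELP1 mRNA, CTCAGTT lies at bases 321 to 327 and GCCTTGA at 705 to 711 and 1864 to 1870. This is too far apart for 1 short siRNA to match both, and whether a pool was used is not given. The loss of PELP1 stays open, the siRNA sequences are not given in the sources used here, and with the carriers left out and the preset correlation 8 of 14 list calls held, among them ATF4 and NF-kB, while those of mitosis (median 0.095 before and 0.0998 after), p53 (-0.099 and -0.11), ERK (-0.20 and -0.15), TGF-beta (-0.22 and -0.17) and anti-apoptotic genes (-0.28 and -0.17) were lost with fewer members tested, so their loss alone does not speak for the words as the cause (0 of the 14 held with an estimated correlation).

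Respiratory chain genes had a median log2 fold change of 0.21, with 21 of 44 higher, 1 lower and 22 not past the threshold, and the list was not called with an estimated correlation (adjusted p = 0.652) or by fry (0.145). A length and GC trend as the whole cause is excluded, since the median was 0.145 after its removal. A shift of the whole list between single libraries may contribute, since its median differed by 0.127 between the PELP1 siRNA libraries and by 0.001 between the control libraries. The estimated correlation between its genes was 0.633. An effect of PELP1 stays open and was not tested apart from that shift.

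Genes of cholesterol and fatty acid synthesis had a median log2 fold change of 0.50 over 36 genes, and a length and GC trend is excluded, since the median was 0.562 after its removal. Of the 24 risen members with a 3' UTR, 25% carry TGGTGCT, the word of the strongest rise (z = 5.36, upper bound of the share 44.9%). The share goes against direct silencing of all of them by the control siRNA through this word. Indirect effects of such silencing were not tested, so silencing by the control siRNA is not excluded. Its sequence is not given in the sources used here, so silencing through another word cannot be told apart. The highest z of the 370 words carried by at least 8 of these members was 3.72, within 1 of the highest of 20 shuffles (4.33). TGGTGCT is the target word of the microRNA family miR-29; the words of 17 other families had a median z of 0.681 (12 above 0, miR-21 at 0.071), at the 97.34th percentile of random word sets, so a displacement of microRNAs by the PELP1 siRNA may go with this, as a hypothesis, but the control libraries also received an siRNA. For the lipid genes an effect of PELP1 loss stays open as a hypothesis, beside indirect effects of the fallen genes that carry the words, which were not tested.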
